A study of Mus musculus with 9 samples.

How the data were processed

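Messenger RNA of the liver was sequenced in 9 libraries from C57BL/6J mice, 3 in each of 3 groups named WT, Con A and FMT-Con A. The values used are read counts per gene, 1 deposited file per library, with no normalisation: the files hold whole numbers that sum to 20513051 to 29466806 per library. Per the submitters' processing notes, CASAVA, HISAT2 and featureCounts were used with the mouse build GRCm38 (mm10). Those notes give no tool versions, annotation release, strand setting or treatment of reads that map to several places. Per the labels' protocols, RNA was extracted with Trizol and the libraries were made from polyadenylated RNA and sequenced in both directions on an Illumina instrument. The labels number the mice within a group, and nothing else in them states that the 3 libraries of a group come from separate animals, so the p-values measure the spread between these libraries.

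Each file lists 56719 genes, of which 55359 have an Ensembl identifier and 1360 are numbered gene models without one. Symbols, positions and gene types were taken from the GENCODE vM21 annotation of GRCm38, which paired 52083 of the Ensembl identifiers with a symbol and left 3276 without one. Those numbered gene models held 1.43 to 1.98% of a library's counts, and unmatched identifiers 0.524 to 1.15%. Positions are counted from 1. Reads from overlapping or near-identical genes (Saa1 and Saa2, Reg3b and Reg3g, the Mup genes, the globins, Tgtp1 and Tgtp2) and from antisense partners cannot be told apart from these counts, since the counting settings are not stated.

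All 9 libraries were fitted together in edgeR 4.0.16 under R 4.3.3 with TMM normalisation, which left 6 residual degrees of freedom. The group-aware filterByExpr filter (minimum count 10, minimum total 15) kept 17704 genes, 16802 of them with a symbol. Each pair of groups was compared with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the 17704 genes and a threshold of 0.05. These adjusted values are called edgeR adjusted p. Standard errors (SE) of log2 fold changes are the absolute log2 fold change over the square root of F. The log2 fold changes use edgeR's prior count of 0.125. Expression levels are counts scaled to library size and TMM factor (CPM), given as mean ± SD over the 3 libraries of a group. Principal components were computed from log2 CPM with a prior count of 2. Where a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its 95% counting interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

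Before the data were examined, the comparisons, the tests, a set of gene lists and the rule for naming genes were fixed. The lists were 25 pathways, 12 sets of cell type markers, 2 sets of liver zonation genes and 2 check lists, for the sex of the animals and for mitochondrial transcripts. The exocrine pancreas list had 0 of its 10 genes above the count filter and was not tested. The other 38 were tested as sets with limma's camera (limma 3.58.1), two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment within a comparison, and again with a correlation estimated per list. A list needed 3 tested members. The check lists were not tested as sets. Counts "adjusted over the list alone" use Benjamini-Hochberg adjustment over the list's members only. After the counts had been seen, 6 more lists were added (skeletal muscle, cardiac muscle, ubiquitously expressed control genes, male-biased and female-biased liver genes, complement), tested as a family of their own. Tf and Ahsp, and C5 of the added complement list, matched no symbol.

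Named genes follow a rule in 4 parts. Part 1 takes, per comparison, the 8 largest rises and the 8 largest falls among genes that pass the threshold, change at least 2-fold, reach 5 CPM in the higher group and have all libraries of one group above all of the other, leaving out predicted gene models, pseudogenes and receptor segments. Part 2 takes up to 3 members with the lowest p of each list that passed its test or had 3 or more members past the gene threshold. Part 3 takes Ifng, Tnf, Il6, Il10, Cxcl9, Saa1, Hmox1, Cyp7a1, Mki67 and Alb in every comparison, whatever their p. Part 4 takes genes past the threshold in both Con A vs WT and FMT-Con A vs Con A, namely the 5 with the largest changes in each class of opposite directions and the 3 in each class of equal directions. Not every gene that parts 1 and 2 take is given in the text. Outside this rule, some members of a list are named where 5 or fewer of them stood apart in direction or missed the threshold, and they were chosen after their values were seen, as were the members named from the 6 added lists.

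Each library was also placed on an axis from the WT mean (0) to the Con A mean (1). For each Con A library in turn, the axis genes and their fold changes came from the WT and the other Con A libraries, and the left-out Con A library and the FMT-Con A libraries were placed on it. The positions were compared with an exact two-sided permutation test. Genes past the threshold in Con A vs WT and, in the opposite direction, in FMT-Con A vs Con A were counted and set beside 20 simulations in which FMT-Con A was drawn as unchanged Con A.

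The fits were tested on simulated counts with known changes, each gene drawn on its own from the real means and library sizes (17704 genes). For Con A vs WT, 2.99, 37.3 and 75.8% of the 67, 67 and 66 genes changed 1.5-, 2- and 4-fold were recovered. The shares were 4.48, 23.9 and 75.8% for FMT-Con A vs Con A, and 2.99, 28.4 and 84.8% for FMT-Con A vs WT. Unchanged genes called numbered 6, 2 and 7 in those comparisons. A simulated list shifted upwards was recovered in each (camera adjusted p = 1.46e-18, 3e-17 and 4.35e-21), and 0 of 30 unshifted lists were called. This does not test lists of correlated genes. A simulated axis position of 0.6 came back as 0.559, with held-out Con A at 0.913.

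The alternatives tried were DESeq2's size factors, no count filter, the DESeq2 Wald test (version 1.42.0), limma voom with sample quality weights, only the libraries of the groups compared, a fold change minimum, a replicate block, fry and an estimated correlation for the lists, the 500 genes with the lowest p for the axis, and each library left out in turn (for the axis, of WT and FMT-Con A). Added after the data were seen were a covariate for skeletal muscle transcripts, FMT-Con A 1 and 3 summed into 1 library, FMT-Con A 1 and 3 both removed and, for the axis, each Con A library left out in turn. No library was left out of the values reported.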

Results

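Liver transcripts were counted in 9 mouse libraries, 3 from each of 3 groups. Con A mice received concanavalin A, a plant lectin that activates T cells and injures the mouse liver, by tail vein (10 mg/kg) on the day the livers were taken. FMT-Con A mice received the same injection after 4 weeks of oral transfer of faeces from mice with concanavalin A hepatitis, a model of autoimmune hepatitis. WT mice received saline throughout, and Con A mice saline in place of the faeces. The series asks which genes and signalling pathways bear on self-healing of the liver. Total counts ran from 20513051 to 22770276 in WT, 21772376 to 25890947 in Con A and 21580482 to 29466806 in FMT-Con A, and 17704 genes were tested.

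On the first principal component (68.2% of the variance) the WT libraries lay between -145.42 and -142.42, and the 6 libraries of injected mice between 50.84 and 92.2. The second component (18.5%) placed Con A at -92.61, -70.01 and -15.02 and FMT-Con A at 76.06, 15.8 and 76.09. Transcripts of the mitochondrial genome took 21.6, 22.4 and 19.6% of the counts in WT, 5.86, 9.96 and 5.03% in Con A and 10.8, 7.44 and 11.7% in FMT-Con A. A list of 24 skeletal muscle genes, drawn up after the counts had been seen, summed to 53.9, 39.7 and 57.3 CPM of the library total (without TMM factors) in WT. It summed to 10.9, 21.1 and 2250 in Con A, and to 21500, 1980 and 21500 in FMT-Con A. FMT-Con A 1 and 3 were the closest pair of libraries, with a median chi-square 2.53 times that of sampling. It was 3.08 for WT 1 and 2 and 9.9 and 9.84 for the other FMT-Con A pairs. Con A 2 was nearer to FMT-Con A 2 (9.85) than to Con A 1 (10.2) or 3 (12.5). Con A 1 and 3 lay 6.55 apart and 16.8 or more from FMT-Con A.

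**Figure D1:**
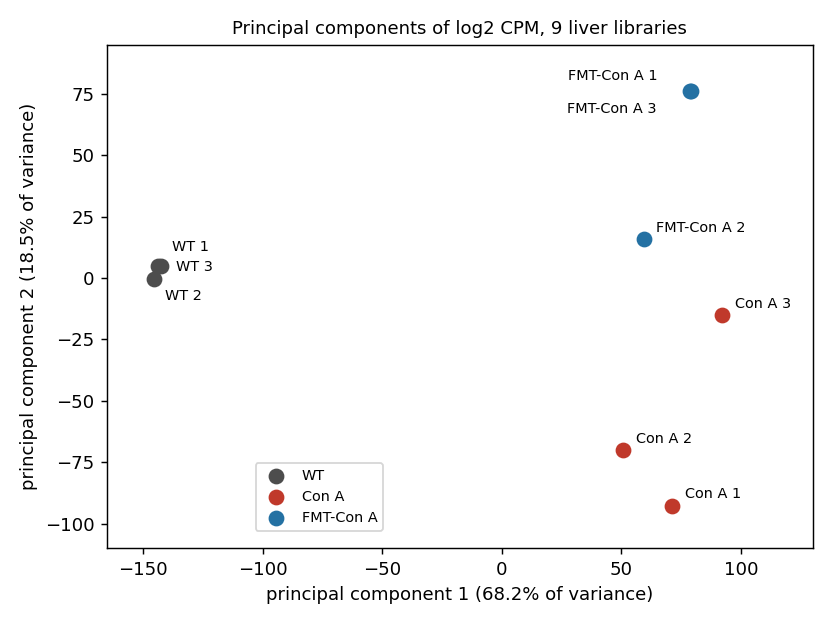
Principal components 1 and 2 of log2 CPM of the 9 liver libraries, 1 point per library, coloured by group. Component 1 (68.2% of the variance) parts WT from the injected groups. Component 2 goes with muscle as well as group, and FMT-Con A 1 and 3 coincide.

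**Figure D2:**
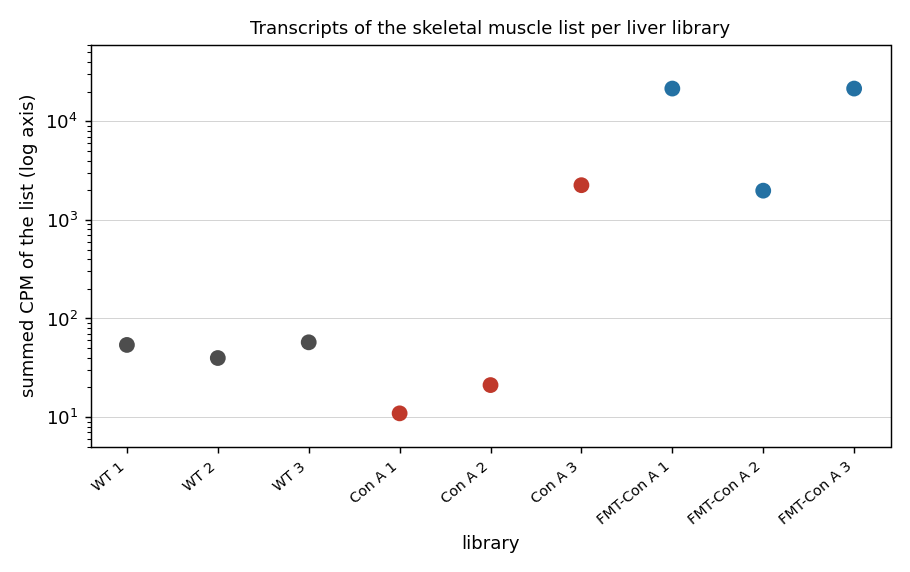
Summed CPM of the 24 skeletal muscle list genes in each library, on a log axis, coloured by group. Con A 3 and the FMT-Con A libraries lie above the highest WT library (57.3).

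Con A vs WT compares the injection alone with saline. All tested interferon-gamma targets, acute phase genes and neutrophil markers rose, as did 21 of 23 cytokines and chemokines. Of 13 lipogenesis genes 8 fell, and of 18 bile acid genes 9 fell and 5 rose. With an estimated correlation, of these lists only the interferon-gamma response was called. Nos2, the inducible nitric oxide synthase, went from 0.224 ± 0.0133 CPM in WT to 261 ± 64.9 in Con A, a log2 fold change of 10.15 (SE 0.33, n = 3 each, edgeR adjusted p = 6.9e-08). Lcn2, which encodes an iron-sequestering acute phase protein, went from 13.2 ± 1.28 to 6790 ± 731 CPM (log2 fold change 9.01, SE 0.3, edgeR adjusted p = 6.9e-08). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 104 ± 24.3 to 0.185 ± 0.0787 CPM (log2 fold change -9.07, SE 0.35, edgeR adjusted p = 1.03e-07). In all, 11219 genes passed the threshold (63.4% of those tested), 5749 higher and 5470 lower in Con A, and 7622 of them changed at least 2-fold. The libraries of the groups did not overlap for 69.8% of genes, where chance gives 10%.

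Among the largest rises, Sele, an endothelial adhesion molecule for leukocytes, had 0 counts in WT and 16 ± 8.48 CPM in Con A, at least 353-fold higher (edgeR adjusted p = 1.69e-05). Ptgs2, the inducible cyclooxygenase, was 1340 times higher by counts (95% counting interval 239 to 52800), and Olr1, a scavenger receptor, 1250 times (345 to 10300). Reg3b and Reg3g, near-identical in part, were at least 134-fold and at least 120-fold higher. Among the falls, Nr1i3 (the nuclear receptor CAR) went from 130 ± 8.41 to 2.27 ± 0.839 CPM (log2 fold change -5.84, SE 0.24, edgeR adjusted p = 1.57e-07). Nr1h5 was lower by a count ratio of 222 (75.7 to 1080), and Tmem25, Elf5, Nrep, Sema5b and Rgr fell by 6.14, 6.07, 6.05, 5.99 and 5.88 on the log2 scale. On GRCm38, Nos2 (ENSMUSG00000020826) lies on chromosome 11 at 78920787 to 78960254. Lcn2 (ENSMUSG00000026822) lies on chromosome 2 at 32384633 to 32388252. Sele (ENSMUSG00000026582) lies on chromosome 1 at 164048234 to 164057677, Cyp7a1 (ENSMUSG00000028240) on chromosome 4 at 6265612 to 6275633 and Nr1i3 (ENSMUSG00000005677) on chromosome 1 at 171213970 to 171220701.

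All 28 genes of the interferon-gamma response rose (28 adjusted over the list alone), with a median log2 fold change of 4.24 (camera adjusted p = 8.71e-35, and adjusted p = 0.0275 with an estimated correlation). Cxcl9, a T cell chemoattractant induced by interferon-gamma, went from 27.3 ± 6.8 to 5520 ± 943 CPM (log2 fold change 7.66, SE 0.29), and Gbp5 rose by 6.88 on the log2 scale. Ifng itself went from 0.168 ± 0.141 to 15.2 ± 2.95 CPM (log2 fold change 6.49, SE 0.41, edgeR adjusted p = 1.33e-06). Of the 22 type I interferon response genes 21 rose (21 adjusted over the list alone, median 2.97, camera adjusted p = 1.36e-10, and adjusted p = 0.154 with an estimated correlation), among them Oasl2 (3.1), Zbp1 (3.71) and Mx1 (1.77). Oas2 did not pass (log2 fold change -0.31, edgeR adjusted p = 0.0812). Of 23 cytokines and chemokines 21 rose, Il18 fell and Il4 did not pass (21 higher and 1 lower adjusted over the list alone), with a median of 4.86 (camera adjusted p = 1.8e-11, and adjusted p = 0.0907 with an estimated correlation). Ccl7 rose by 7.73, Ccl4 by 5.26, Tnf by 4.37 and Il10 by 2.87 on the log2 scale, and Il6 was 42.8 times higher by counts (14.3 to 210). Cxcl9 (ENSMUSG00000029417) lies on chromosome 5 at 92321347 to 92328079. Gbp5 (ENSMUSG00000105504) lies on chromosome 3 at 142493978 to 142522344 and Ifng (ENSMUSG00000055170) on chromosome 10 at 118441046 to 118445892.

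All 16 NF-kappaB targets and adhesion genes rose (16 adjusted over the list alone, median 2.92, camera adjusted p = 2.57e-13, and adjusted p = 0.12 with an estimated correlation), among them Ier3 (7.84) and Tnfaip3 (7.27). So did all 25 acute phase genes (25 adjusted over the list alone, median 4.32, camera adjusted p = 1.21e-30, and adjusted p = 0.0684 with an estimated correlation). Saa1 went from 32.6 ± 4.85 to 8850 ± 2240 CPM and Saa2 from 19.9 ± 1.46 to 9370 ± 2160, though reads of this pair may be split between them. Of 19 bacterial sensing genes 15 rose, Tlr5 fell and Tlr1, Tlr7 and Tlr8 did not pass (15 higher and 2 lower adjusted over the list alone, median 1.21, camera adjusted p = 5.97e-06, and adjusted p = 0.0907 with an estimated correlation). Tlr2, a sensor of bacterial lipoproteins, rose by 6.79 on the log2 scale. Of the 12 antigen presentation (MHC) genes 9 rose and B2m, H2-DMa and H2-DMb1 did not pass (10 higher adjusted over the list alone, median 0.94, camera adjusted p = 0.00461, and adjusted p = 0.427 with an estimated correlation). Of 11 T cell checkpoint genes 9 rose, among them Ctla4 (4.19), while Lag3 and Icos did not pass (9 adjusted over the list alone, median 1.63, camera adjusted p = 0.00692, and adjusted p = 0.16 with an estimated correlation). Saa1 (ENSMUSG00000074115) lies on chromosome 7 at 46740497 to 46742980 and Saa2 (ENSMUSG00000057465) on chromosome 7 at 46751790 to 46754313.

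Cell death genes rose in 18 of 22 cases (18 adjusted over the list alone, median 1.45, camera adjusted p = 2.55e-11, and adjusted p = 0.0831 with an estimated correlation), among them Mlkl, the effector of necroptosis (3.6), and Tnfrsf12a (4.58). Casp1, Casp8, Casp12 and Pycard did not pass. All 13 p53 targets rose (13 adjusted over the list alone, median 2.93, camera adjusted p = 1.24e-08, and adjusted p = 0.0831 with an estimated correlation), with Cdkn1a, which stops the cell cycle, at 7.16 and Gdf15 at 6.9. Of 16 unfolded protein response genes 12 rose (12 adjusted over the list alone, median 1.5, camera adjusted p = 8.54e-05, and adjusted p = 0.16 with an estimated correlation), while Hsp90b1, Sdf2l1, Herpud1 and Calr did not pass. Immediate early and regeneration priming genes rose in 15 of 19 cases (15 adjusted over the list alone, median 3.57, camera adjusted p = 3.82e-11, and adjusted p = 0.0907 with an estimated correlation), led by Atf3 (8.15) and Btg2 (7.3). Myc, Hgf, Met and Il6ra did not pass. Of 13 glycolysis and hypoxia genes 12 rose, with Pdk1 not passing (12 higher and 1 lower adjusted over the list alone, median 3.68, camera adjusted p = 1.05e-07, and adjusted p = 0.132 with an estimated correlation), among them Adm (7.57) and Slc2a1, the glucose carrier GLUT1 (4.11). Of 17 coagulation and fibrinolysis genes 11 rose, Proc fell and Plat, F5, F7, F9 and Serpinc1 did not pass (11 higher and 1 lower adjusted over the list alone, median 1.15, camera adjusted p = 0.000324, and adjusted p = 0.172 with an estimated correlation).

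Bile acid synthesis and transport was called down (camera adjusted p = 0.0177, 0.0532 without Con A 2, and adjusted p = 0.531 with an estimated correlation), with 9 of 18 genes lower, 5 higher and 4 not passing, also when adjusted over the list alone (median -0.76). The risers were Cyp7b1, Cyp2c70, Baat, Abcc4 and Slc51b, and Nr0b2, which encodes the bile acid-induced repressor SHP, fell by 4.23 on the log2 scale. Of 13 lipogenesis genes 8 fell and 0 rose, with Acacb, Scd1, Me1, Thrsp and Dgat2 not passing (8 lower adjusted over the list alone, median -1.26, camera adjusted p = 0.00692, and adjusted p = 0.427 with an estimated correlation). Mlxipl, the carbohydrate-sensing regulator ChREBP, went from 1060 ± 81.4 to 157 ± 40.7 CPM (log2 fold change -2.75, edgeR adjusted p = 4.29e-06), and Srebf1 fell by 1.59.

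Of the marker lists, all 13 neutrophil genes rose (13 adjusted over the list alone, median 5.75, camera adjusted p = 1.55e-12, and adjusted p = 0.121 with an estimated correlation), S100a8 by 5.75 and S100a9 by 5.94. Of 21 T and NK cell genes 14 rose, Cd4 fell and 6 did not pass (15 higher and 1 lower adjusted over the list alone, median 2.03, camera adjusted p = 0.00247, and adjusted p = 0.531 with an estimated correlation). The risers included the cytotoxic granule genes Gzmb (4.94), Gzma (4.62) and Prf1 (3.3). Of 12 monocyte and infiltrating macrophage genes 8 rose, Ccr2 and Cx3cr1 fell, and Lyz2 and Fcgr1 did not pass (8 higher and 2 lower adjusted over the list alone, median 1.78, camera adjusted p = 0.00805, and adjusted p = 0.107 with an estimated correlation).

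The other 19 lists were not called in this comparison, though most held genes that moved. Heat shock genes rose in 4 of 11 cases (Hspa1a, Hspa1b, Dnajb1 and Bag3) and Chordc1 fell (camera adjusted p = 0.564). NRF2 and oxidative stress genes moved both ways, 6 higher and 4 lower of 15 (median -0.5, mean 0.48, test direction up, camera adjusted p = 0.597), with the haem-degrading Hmox1 up by 5.9 and the falls in Gclc, Gclm, Gsta1 and Osgin1. Of 25 cell cycle genes 6 rose and 4 fell (camera adjusted p = 0.92), the replication genes Mcm4 (1.89) and Pcna (1.02) among the risers and Ccnb2, Aurka, Birc5 and Tk1 the falls. Mki67, a proliferation marker, had a log2 fold change of -0.18 (edgeR adjusted p = 0.559), and 0.15 without WT 2. Of 18 xenobiotic cytochromes P450, 8 fell and Cyp2b10, Cyp2c29 and Cyp2c37 rose (camera adjusted p = 0.597). Fatty acid oxidation genes (5 higher and 9 lower of 23, camera adjusted p = 0.492), cholesterol synthesis genes (8 higher and 2 lower of 21, Stard4 among the falls, camera adjusted p = 0.403) and urea cycle and amino acid breakdown genes (8 higher and 5 lower of 17, camera adjusted p = 0.92) went both ways. In glucose handling, Fbp1, Pcx, Igfbp1 and Irs2 rose and 6 of 11 fell, Igfbp1 at 7.86 (camera adjusted p = 0.597, test direction down, median -0.7, mean 0.06). Of 17 circadian clock genes 9 rose and 6 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.775), with Nr1d1, a clock repressor, going from 10.5 ± 4.14 to 122 ± 37.4 CPM and Hlf falling by 3.26.

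Resident liver cells gave mixed markers. Among 12 Kupffer cell genes Marco, Adgre1 and C1qc rose and Clec4f, Vsig4, Cd163 and Slc40a1 fell (camera adjusted p = 0.941, test direction down, median -0.03, mean 0.02). Sinusoidal endothelial genes split into 6 higher and 6 lower of 15 (camera adjusted p = 0.92), with Lyve1 at 2.93 and Clec4g at -2.19. In the stellate cell and matrix list Timp1, an inhibitor of matrix breakdown (6.88), and Lox rose and Col1a2 and Lrat fell of 15 (camera adjusted p = 0.92, test direction up, median -0.01, mean 0.73). Cholangiocyte genes rose in 5 of 7 cases, with 1 lower and Krt7 not passing (camera adjusted p = 0.751). Among 13 hepatocyte genes 5 rose and 4 fell (camera adjusted p = 0.945, test direction up, median -0.13, mean 0.21), and Alb, which encodes albumin, was at 35400 ± 2290 CPM against 38800 ± 5870 in WT (log2 fold change -0.13, edgeR adjusted p = 0.593). Of 11 B and plasma cell genes Pax5 and Mzb1 fell (camera adjusted p = 0.775, test direction down, median 0.17, mean -0.21). Of 7 erythroid genes 4 rose, among them Hbb-bs, Hbb-bt and Slc4a1 (camera adjusted p = 0.157), and of 7 adipocyte genes Cidec and Plin4 (camera adjusted p = 0.775, test direction up, median -1.54, mean -0.63). Of 11 pericentral genes Glul and Oat rose and 5 fell (camera adjusted p = 0.283), including Lgr5, a Wnt target of hepatocytes next to the central vein, from 4.41 ± 0.817 to 0.279 ± 0.0468 CPM (log2 fold change -3.95, edgeR adjusted p = 7.15e-06). Of 11 periportal genes 4 rose and 5 fell (camera adjusted p = 0.316). All 9 mitochondrial transcripts fell (median -1.51), mt-Co1 from 66700 ± 4870 to 26100 ± 7060 CPM. Adjusted over the list alone, the counts of these uncalled lists were equal to those given, except for heat shock (3 higher), cholesterol synthesis (1 lower), the clock (7 lower), B and plasma cells (1 lower), sinusoidal endothelium (7 lower) and stellate cells (1 lower).

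The count of genes stayed between 9937 and 12101 with 1 library left out. With an estimated correlation the interferon-gamma response remained called and the other 18 lists did not, and other splits of the 6 libraries gave up to 22 called lists against 19 for the groups as labelled.

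**Figure D3:**
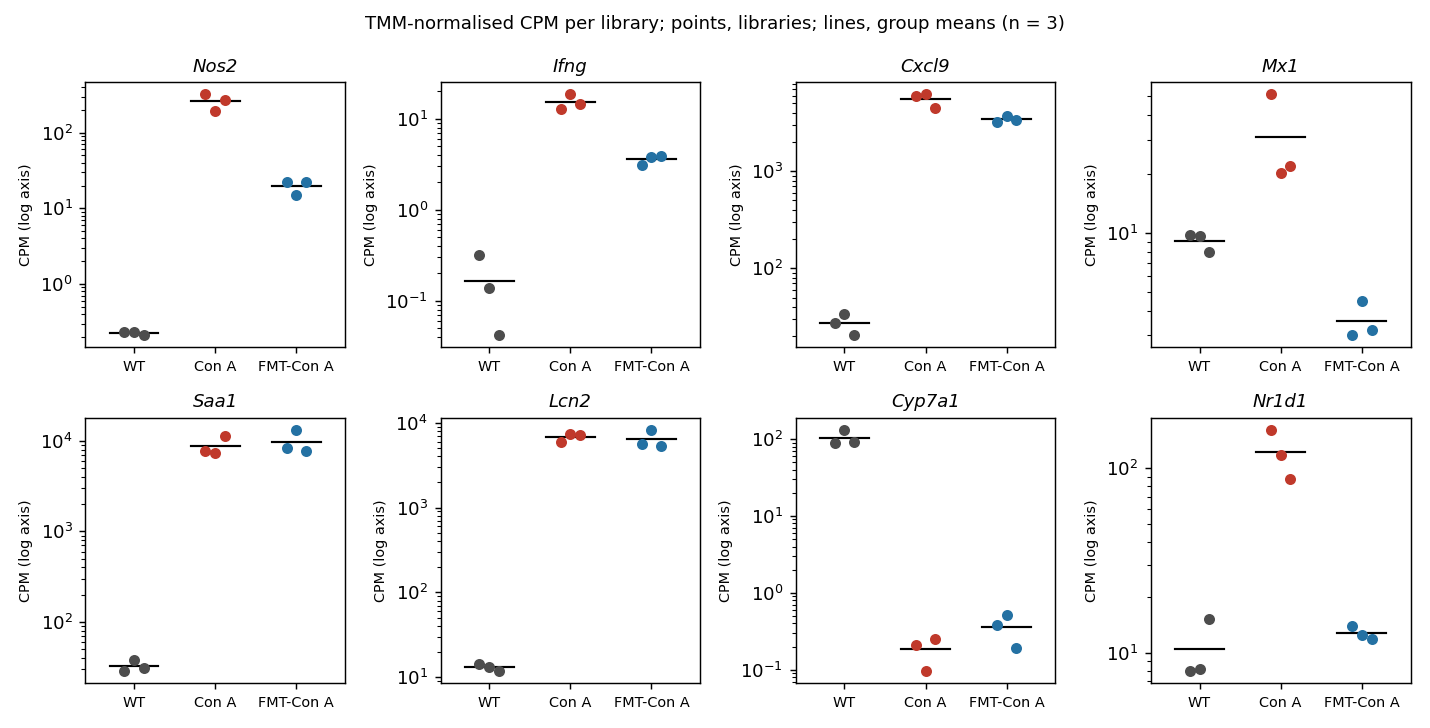
TMM-normalised CPM of 8 genes in each library, on log axes, with points for libraries and lines for group means (n = 3). Nos2, Ifng, Mx1 and Nr1d1 are lower in every FMT-Con A library than in every Con A library, while the ranges of the groups overlap for Saa1 and Lcn2.

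FMT-Con A vs Con A compares livers with and without the faecal transfer after the same injection. After the transfer 21 of 22 type I interferon response genes, 13 of 28 interferon-gamma targets and 11 of 23 cytokines and chemokines were lower, as were the cytotoxic granule genes Gzma, Gzmb and Prf1. Of 25 acute phase genes 22 did not pass, and 4 of 23 skeletal muscle genes were higher. With an estimated correlation 0 of the 38 lists fixed beforehand were called, against 23 with the preset one and 22 by fry, nor was the muscle list (adjusted p = 0.263). Mx1, an interferon-induced antiviral GTPase, fell from 31 ± 17.3 to 3.57 ± 0.82 CPM (log2 fold change -3.12, SE 0.36, n = 3 each, edgeR adjusted p = 0.00199). Nos2 fell from 261 ± 64.9 to 19.7 ± 4.11 CPM (log2 fold change -3.72, SE 0.23, edgeR adjusted p = 0.000314) and Ifng from 15.2 ± 2.95 to 3.59 ± 0.405 CPM (log2 fold change -2.09, SE 0.29, edgeR adjusted p = 0.00353). Saa1 had a log2 fold change of 0.15 (edgeR adjusted p = 0.733), and -0.13 without FMT-Con A 2. In all, 2981 genes passed (16.8%), 1108 higher and 1873 lower in FMT-Con A, 1443 of them by at least 2-fold, and the libraries of the groups did not overlap for 32.7% of genes, where chance gives 10%.

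The count depended on single libraries: it was 664 without FMT-Con A 1, 778 without FMT-Con A 3, 812 without Con A 1 and 1828 without WT 1, and of 111 named genes 45, 42 and 42 lost their call without FMT-Con A 1, FMT-Con A 3 and Con A 1. It was 450 with skeletal muscle transcripts as a covariate (344 shared with the 2981), 766 with FMT-Con A 1 and 3 summed into 1 library (765 shared) and 99 with both removed (85 shared), choices made after the data were seen. Of the 111 named genes 74 lost their call with the covariate, 42 with the pair summed and 92 with both removed. With the covariate they included Ifng (log2 fold change -1.99, edgeR adjusted p = 0.0529), Prf1 (-2.51, 0.0529), Gzmb (-1.4, 0.0672), Mup4 (-9.6, 0.0857), Elovl3 (-3.22, 0.0687), Cps1 (-1.61, 0.102) and the 8 largest rises (1.24 to 2.89, 0.161 to 0.589). With both removed Mx1 (-2.78, 0.0784), Oasl2 (-1.17, 0.0637) and Gzma (-2.31, 0.0566) lost theirs as well.

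The 8 largest rises named were Lrrc30, Actn3, Sgca, Shisa4, Mylk4, Tbx15, Mstn and Txlnb, with log2 fold changes of 4.66 to 5.58. Several of them encode muscle proteins, such as the fast-fibre actinin Actn3, the sarcoglycan Sgca and myostatin (Mstn). Actn3 was at 213 ± 156 CPM against 5.7 ± 9.35 in Con A (log2 fold change 5.2, edgeR adjusted p = 0.0312). Its edgeR adjusted p was 0.0563, 0.0513 and 0.0513 without WT 1, 2 and 3, 0.083 without Con A 1, and 0.0874 and 0.0805 without FMT-Con A 1 and 3. For the others the edgeR adjusted p was 0.0569 to 0.111 without Con A 1 and 0.0566 to 0.12 without FMT-Con A 1. Without FMT-Con A 3 it was 0.0617 to 0.114 for all of these but Shisa4, which passed. Txlnb and Mylk4 also lost their calls without WT 1 (0.069 and 0.0746), WT 2 (0.0633 and 0.0561), WT 3 (0.0778 and 0.0545) or Con A 2 (0.0595 and 0.0506), and Tbx15 without WT 1 (0.057). Of 23 tested genes of the skeletal muscle list Tnnt1, Actn3, Pvalb and Neb rose and 19 did not pass, 12 rising when adjusted over the list alone (median 3.99, camera adjusted p = 5.87e-10, and adjusted p = 0.263 with an estimated correlation). The adipocyte list also rose (camera adjusted p = 0.0222, and 0.433 with an estimated correlation, median 2.91). Cfd was higher and 6 genes did not pass, with 4 rising when adjusted over the list alone. Cfd lost its call without WT 1 (edgeR adjusted p = 0.0542), Con A 1 (0.12), Con A 3 (0.0829), FMT-Con A 1 (0.105) or FMT-Con A 3 (0.0927), and Pvalb without each library but Con A 3 and FMT-Con A 2 (0.0584 to 0.113). Its camera adjusted p was 0.0902 without Con A 2, 0.0671 without Con A 3 and 0.407 with the muscle covariate. Adipoq (adiponectin) was at 12.6, 1.62 and 11.6 CPM in FMT-Con A 1, 2 and 3 (muscle 21500, 1980 and 21500). It did not follow muscle in Con A 3 (0.463, muscle 2250) or WT 2 (4.64, muscle 39.7).

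The largest falls were in Mup4 (from 156 ± 92.2 to 0.484 ± 0.758 CPM, log2 fold change -8.17, edgeR adjusted p = 0.00501), a major urinary protein gene with near-identical relatives, and Elovl3, a fatty acid elongase (from 23.3 ± 14.5 to 1.18 ± 1.04 CPM, log2 fold change -4.38, edgeR adjusted p = 0.00413). Gml, Duox2, Nos2, Nr1d1 and Ifit2 fell by 4.33, 3.9, 3.72, 3.26 and 3.2 on the log2 scale. Mup4 (ENSMUSG00000041333) lies on chromosome 4 at 59956804 to 59960710. Elovl3 (ENSMUSG00000038754) lies on chromosome 19 at 46131897 to 46135694 and Nr1d1 (ENSMUSG00000020889) on chromosome 11 at 98767932 to 98775333.

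Type I interferon response genes fell in 21 of 22 cases (22 adjusted over the list alone), with a median log2 fold change of -1.43 (camera adjusted p = 1.27e-20, and adjusted p = 0.108 with an estimated correlation). Zbp1 did not pass (log2 fold change -0.6, edgeR adjusted p = 0.0832). Oasl2 went from 159 ± 3.97 to 58.9 ± 10.3 CPM (log2 fold change -1.44, edgeR adjusted p = 0.00196), and Ifi44 fell by 1.73. Of 28 interferon-gamma response genes 13 fell and 0 rose (18 lower adjusted over the list alone, median -0.72, camera adjusted p = 1.52e-09, and adjusted p = 0.13 with an estimated correlation), with Gbp5 going from 489 ± 88.1 to 142 ± 21.2 CPM (log2 fold change -1.78, edgeR adjusted p = 0.00147). Cxcl9 did not pass (3420 ± 219 against 5520 ± 943 CPM, log2 fold change -0.69, edgeR adjusted p = 0.0564), and its edgeR adjusted p was 0.0423 without Con A 3. Of 23 cytokines and chemokines 11 fell and 0 rose (14 lower adjusted over the list alone, median -1.22, camera adjusted p = 7.36e-08, and adjusted p = 0.13 with an estimated correlation), Ccl4 by 1.74. Il6 (log2 fold change -1.71, edgeR adjusted p = 0.0308) lost its call without WT 2 (0.0523), Con A 1 (0.132), Con A 3 (0.0525), FMT-Con A 1 (0.113), 2 (0.0523) or 3 (0.0838). Il10 (-1.53, 0.0338) lost it without WT 1 (0.0564), WT 3 (0.0552), Con A 1 (0.117), Con A 2 (0.0703), FMT-Con A 1 (0.136) or FMT-Con A 3 (0.128). Tnf did not pass (log2 fold change -1.03, edgeR adjusted p = 0.0664), and its edgeR adjusted p was 0.0321 without Con A 3. Mx1 (ENSMUSG00000000386) lies on chromosome 16 at 97447035 to 97462907.

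NF-kappaB targets and adhesion genes fell in 8 of 16 cases (13 adjusted over the list alone, median -0.82, camera adjusted p = 7.94e-07, and adjusted p = 0.232 with an estimated correlation), with Tnfaip3 at -1.59 and Nfkb1 at -1.06. Of 19 bacterial sensing genes 7 fell (8 lower and 1 higher adjusted over the list alone, median -0.56, camera adjusted p = 0.000119, and adjusted p = 0.141 with an estimated correlation), including Tlr7, a sensor of single-stranded RNA, at -2.28 and Tlr2 at -1.32. Of 12 antigen presentation genes 8 fell and Tap2, Psmb10, H2-DMa and H2-DMb1 did not pass (9 lower adjusted over the list alone, median -0.67, camera adjusted p = 0.000226, and adjusted p = 0.257 with an estimated correlation), with the class II gene H2-Ab1 at -1.05. Of 11 T cell checkpoint genes Ctla4, Tnfrsf9 and Lgals9 fell (7 adjusted over the list alone, median -0.77, camera adjusted p = 0.000691, and adjusted p = 0.141 with an estimated correlation). These falls lost their calls without Con A 1 (edgeR adjusted p = 0.116, 0.0625 and 0.0717), FMT-Con A 1 (0.0997, 0.073 and 0.0717) or FMT-Con A 3 (0.107, 0.0558 and 0.0716). Acute phase genes were not called (median -0.04, camera adjusted p = 0.53), with Hamp, Cp and Il1rn lower and 22 of 25 not passing, also when adjusted over the list alone. Il1rn, the antagonist of the interleukin-1 receptor, fell by 2.3. Hamp and Cp lost their calls without FMT-Con A 1 (edgeR adjusted p = 0.0624 and 0.0697) or FMT-Con A 3 (0.0663 and 0.0613), and Hamp without Con A 1 (0.0675).

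Among stress and injury lists, 10 of 22 cell death genes fell (12 adjusted over the list alone, median -0.42, camera adjusted p = 3.93e-06, and adjusted p = 0.13 with an estimated correlation), such as the death receptor Tnfrsf10b (-1.84) and Mlkl (-1). Of 13 p53 targets 9 fell and Cdkn1a, Ccng1, Phlda3 and Pmaip1 did not pass (10 lower adjusted over the list alone, median -0.96, camera adjusted p = 5.94e-08, and adjusted p = 0.108 with an estimated correlation), Trp53inp1 at -2.17 and Mdm2 at -1.18. Of 15 NRF2 and oxidative stress genes 8 fell (8 adjusted over the list alone, median -1.03, camera adjusted p = 2.31e-06, and adjusted p = 0.108 with an estimated correlation), including Nfe2l2, which encodes NRF2 (-1.64), Srxn1 (-1.21) and Hmox1 (-1.27). Of 19 immediate early and regeneration priming genes 13 fell (15 adjusted over the list alone, median -0.92, camera adjusted p = 1.52e-09, and adjusted p = 0.108 with an estimated correlation), among them the growth factor genes Areg (-2.75) and Tgfa (-1.65). Of 13 glycolysis and hypoxia genes 9 fell and Hk2, Pdk1, Ldha and Pgk1 did not pass (11 lower and 1 higher adjusted over the list alone, median -0.79, camera adjusted p = 6.87e-05, and adjusted p = 0.232 with an estimated correlation), with Adm at -2.42 and Slc2a1 at -1.71. Of 17 coagulation and fibrinolysis genes 6 fell (7 adjusted over the list alone, median -0.39, camera adjusted p = 0.000181, and adjusted p = 0.184 with an estimated correlation). F11, coagulation factor XI, went from 178 ± 30.1 to 43.2 ± 5.07 CPM (log2 fold change -2.04, SE 0.16, edgeR adjusted p = 0.00147), and F3, tissue factor, fell by 2.94. F11 (ENSMUSG00000031645) lies on chromosome 8 at 45241174 to 45262031.

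T and NK cell genes fell in 8 of 21 cases (9 adjusted over the list alone, median -0.84, camera adjusted p = 1.18e-05, and adjusted p = 0.257 with an estimated correlation). Gzma, a granule protease of cytotoxic lymphocytes, went from 14.9 ± 1.97 to 2.7 ± 0.251 CPM (log2 fold change -2.46, SE 0.25, edgeR adjusted p = 0.00147), and Prf1 and Gzmb fell by 2.61 and 1.67. Of 12 Kupffer cell genes Cd5l, Adgre1 and Slc40a1 fell (8 adjusted over the list alone, median -0.71, camera adjusted p = 0.000357, and adjusted p = 0.287 with an estimated correlation), a call lost with the muscle covariate (camera adjusted p = 0.257). Cd5l and Adgre1 lost their own calls without Con A 1 (edgeR adjusted p = 0.0892 and 0.0755), Con A 3 (0.0601 and 0.0542), FMT-Con A 1 (0.103 and 0.095) or FMT-Con A 3 (0.0933 and 0.0832), and Slc40a1 without FMT-Con A 1 (0.0515). Of 13 neutrophil genes Mmp8 and Ngp fell (2 adjusted over the list alone, median -0.45, camera adjusted p = 0.0121, and adjusted p = 0.468 with an estimated correlation). That call was lost without Con A 2 (camera adjusted p = 0.273), without FMT-Con A 1 (0.0796), with FMT-Con A 1 and 3 summed (0.0742) and with the muscle covariate (0.713). Ngp lost its own call without Con A 1 (edgeR adjusted p = 0.0545), FMT-Con A 1 (0.0761) or FMT-Con A 3 (0.0712). Mmp8 lost it without each library but Con A 3 and FMT-Con A 2 (0.0573 to 0.159). Gzma (ENSMUSG00000023132) lies on chromosome 13 at 113093825 to 113100981.

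Hepatocyte metabolism also held lower genes. Of 17 urea cycle and amino acid breakdown genes 4 fell, among them Cps1, Arg1 and Kmo (4 adjusted over the list alone, median -0.47, camera adjusted p = 0.000659, and adjusted p = 0.393 with an estimated correlation). Of 11 periportal genes Pck1, Cdh1, Arg1 and Cps1 fell (7 adjusted over the list alone, median -0.62, camera adjusted p = 0.00033, and adjusted p = 0.232 with an estimated correlation). Cps1, the first enzyme of the urea cycle, went from 1610 ± 670 to 405 ± 113 CPM (log2 fold change -1.99, edgeR adjusted p = 0.00651). In bile acid synthesis and transport Abcc4 rose and 5 of 18 genes fell, such as the canalicular export pump Abcc2 at -1.56 (1 higher and 7 lower adjusted over the list alone, median -0.52, camera adjusted p = 0.01, and adjusted p = 0.433 with an estimated correlation). Cyp7a1 did not pass (log2 fold change 0.91, edgeR adjusted p = 0.219). Of 18 xenobiotic cytochromes P450 5 fell (10 adjusted over the list alone, median -0.72, camera adjusted p = 0.0159, and adjusted p = 0.468 with an estimated correlation), including Cyp3a11 from 1860 ± 650 to 533 ± 41.6 CPM. The P450 call was lost without Con A 2 (camera adjusted p = 0.1). With the muscle covariate the camera adjusted p was 0.291 for the urea cycle, 0.439 for bile acids and 0.409 for P450 genes. In glucose handling 1 of 11 genes rose and Pck1, G6pc, Pcx and Igfbp1 fell (1 and 4 adjusted over the list alone, median -0.42, camera adjusted p = 0.0314, and adjusted p = 0.36 with an estimated correlation), a call lost without Con A 1 (0.0756) or FMT-Con A 2 (0.0653). Of 17 circadian clock genes Arntl and Cry1 rose and 7 fell (2 and 7 adjusted over the list alone, median -0.48, camera adjusted p = 0.00317, and adjusted p = 0.108 with an estimated correlation), a call lost without FMT-Con A 2 (0.0653). Nr1d1 went from 122 ± 37.4 to 12.7 ± 1.03 CPM (log2 fold change -3.26, SE 0.3, edgeR adjusted p = 0.00147), near its WT level of 10.5 ± 4.14. Cps1 (ENSMUSG00000025991) lies on chromosome 1 at 67123026 to 67231259.

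The remaining lists were not called. In the unfolded protein response Sdf2l1 and Chac1 rose and Ddit3 and Trib3 fell of 16 (camera adjusted p = 0.718). Hspa1a fell among 11 heat shock genes (camera adjusted p = 0.718) and Ccnd1 among 25 cell cycle genes (camera adjusted p = 0.177). In fatty acid oxidation Slc25a20 rose and Ppara and Ehhadh fell of 23 (camera adjusted p = 0.379). Lipogenesis had Pnpla3 higher and Dgat2 lower of 13 (camera adjusted p = 0.718, median -0.16, mean 0). The 21 cholesterol synthesis genes did not pass (camera adjusted p = 0.374, and 0.0224 without Con A 2). Monocyte markers had Ccr2 higher and Ms4a4c lower of 12 (camera adjusted p = 0.811, test direction up, median -0.07, mean -0.1). The 11 B and plasma cell markers did not pass (camera adjusted p = 0.504). Sinusoidal endothelial markers had Stab2 and Dnase1l3 lower of 15 (camera adjusted p = 0.908, test direction down, median 0.12, mean 0.02), and stellate cell and matrix genes Colec10 lower of 15 (camera adjusted p = 0.89, test direction down, median -0.05, mean 0.16). Of 7 cholangiocyte genes 2 rose, among them Sox9 (camera adjusted p = 0.338), and among hepatocyte genes Alb and Apob fell of 13 (camera adjusted p = 0.0635, 0.0254 without Con A 3 and 0.0255 without FMT-Con A 2). Alas2 fell among 7 erythroid genes (camera adjusted p = 0.857), and Axin2 rose among 11 pericentral genes (camera adjusted p = 0.718). The 9 mitochondrial transcripts did not pass (median 0.49). Adjusted over the list alone, the counts of these lists were equal to those given, except for the unfolded protein response (4 higher and 3 lower), cell cycle (0 lower) and hepatocytes (3 lower). Mki67 had a log2 fold change of -0.73 (edgeR adjusted p = 0.0844). Alb was at 19300 ± 1260 CPM against 35400 ± 2290 (log2 fold change -0.88, edgeR adjusted p = 0.0221).

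Of the genes named from these uncalled lists, Alb, Sdf2l1 and Ehhadh lost their calls without Con A 1 (edgeR adjusted p = 0.1, 0.0759 and 0.0723), FMT-Con A 1 (0.0958, 0.0739 and 0.0933) or FMT-Con A 3 (0.0864, 0.0624 and 0.0841). Ddit3 lost it without FMT-Con A 1 (0.0608) or 3 (0.0553), Slc25a20 without Con A 1 (0.0576), and Ppara without each library but Con A 2 and FMT-Con A 2 (0.0672 to 0.158). Uncalled here, 6 lists passed with the muscle covariate. Heat shock (camera adjusted p = 0.0347), lipogenesis (0.0312), sinusoidal endothelium (0.048) and stellate cells (0.00296) were down. Fatty acid oxidation (0.048) and B and plasma cells (0.0255) were up. Of the 23 called lists 1 was up and 22 down, and other splits of the 6 libraries gave up to 21.

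**Figure D4:**
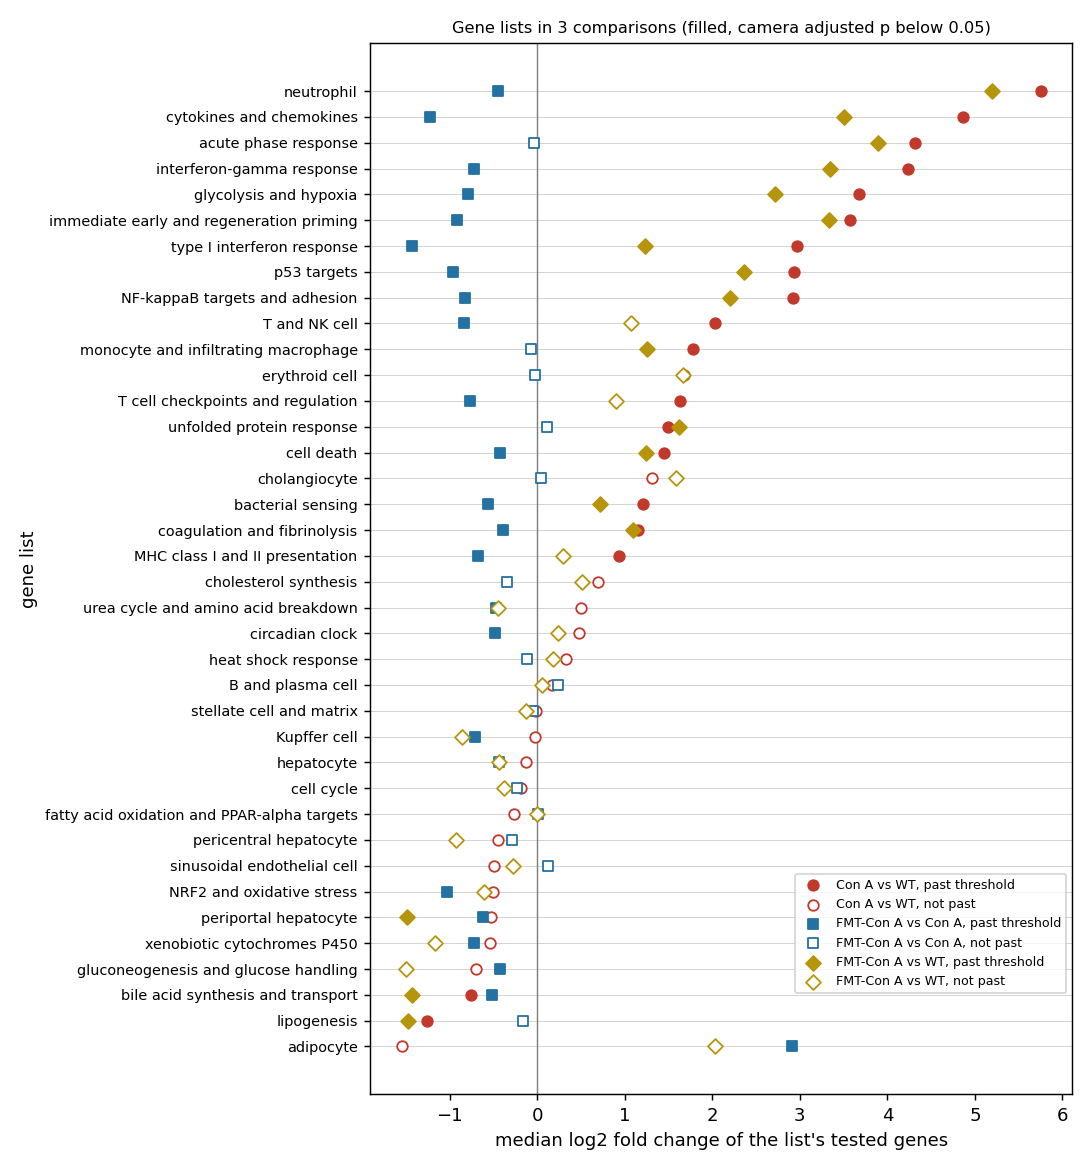
Median log2 fold change of the tested genes of each of 38 gene lists in the 3 comparisons, 1 symbol per comparison, filled where the camera adjusted p passed the threshold. The type I interferon list lies at 2.97 in Con A vs WT and at -1.43 in FMT-Con A vs Con A, and the acute phase list at 4.32 and -0.04.

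An axis from WT (0) to Con A (1) asks how far back FMT-Con A lay. The held-out Con A libraries lay at 1.017, 0.859 and 0.98 (mean 0.952). The FMT-Con A libraries lay at 0.828, 0.823 and 0.828 (mean 0.826), a difference of -0.126. Only the latter are averages over several axes, so the spreads and the test do not treat the groups alike. The exact permutation p was 0.1, the smallest that 3 against 3 can give, and 0.2 with FMT-Con A 1 and 3 summed. Without Con A 1, tried after the data were seen, the difference was -0.036. Of the genes called in Con A vs WT, 1977 (17.6%) also passed in the opposite direction in FMT-Con A vs Con A. Of 5749 risen genes 1387 (24.1%) were lowered, and of 5470 fallen genes 590 (10.8%) were raised. Independent lists would share 951. Another 266 genes moved on in the same direction, against 938. Simulations with unchanged FMT-Con A gave 0.1 and 0.15 on average (at most 1), near 0 by construction, and do not bear on direction. The comparisons share the Con A libraries, and 3 per group are too few to split between them. In the simulations, which share them too but draw each gene on its own, the log2 fold changes of both comparisons correlated at -0.108 on average, against -0.238 observed (covariances -0.0899 and -0.425). Part of the excess of opposite changes may thus come from that sharing. The 1977 became 520 without FMT-Con A 1, 605 without FMT-Con A 3, 612 without Con A 1, 1243 without WT 1 and 3011 without Con A 2. It was 332 with the muscle covariate (265 shared) and 598 with FMT-Con A 1 and 3 summed (597 shared).

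The genes that rose and were then lowered most were Gml, Duox2, Gml2, Nos2 and Mir7678. Duox2, which encodes a hydrogen peroxide-producing oxidase, was 1980 times higher in Con A than in WT by counts (355 to 78300) and fell from 27.5 ± 27.3 to 1.82 ± 0.551 CPM in FMT-Con A (log2 fold change -3.9, edgeR adjusted p = 0.00695). Gml was 177 times higher by counts (48.5 to 1460) and fell by 4.33 on the log2 scale. Gml2, which overlaps Cyp11b1 on the other strand, was at least 81.7-fold higher and then lower by a log2 fold change of -3.73 (edgeR adjusted p = 0.0202). Mir7678, which lies within Slpi, was at least 18.6-fold higher and then at -3.66 (edgeR adjusted p = 0.022). The falls in Gml2 and Mir7678 lost their calls without Con A 1 (0.071 and 0.0857), FMT-Con A 1 (0.0759 and 0.0529) or FMT-Con A 3 (0.0785 and 0.0873). Those that fell and were then raised most were Ptk6, Plet1os, Cep112, Sema6c and Phpt1. Ptk6, an epithelial tyrosine kinase, had 2.7 ± 0.44 CPM in WT, 0 counts in Con A (at least 57.7-fold lower) and 0.41 ± 0.194 CPM in FMT-Con A (at least 9.16-fold higher, edgeR adjusted p = 0.00754). Plet1os, antisense to Plet1, was lower by a count ratio of 17.1 (5.55 to 85.6) and then higher by 21.8 (7.21 to 108), with the later call lost without Con A 1 (0.0587), FMT-Con A 1 (0.0602) or FMT-Con A 3 (0.0546). The later call was also lost for Cep112 without Con A 1 (0.0989), Con A 2 (0.0526), FMT-Con A 1 (0.0764) or FMT-Con A 3 (0.092), and for Phpt1 without Con A 1 (0.101), Con A 2 (0.054) or FMT-Con A 3 (0.0905). For Sema6c it was lost without each library but FMT-Con A 2 (0.0503 to 0.123). Duox2 (ENSMUSG00000068452) lies on chromosome 2 at 122279247 to 122298449. Gml (ENSMUSG00000068349) lies on chromosome 15 at 74813452 to 74818815 and Ptk6 (ENSMUSG00000038751) on chromosome 2 at 181193721 to 181202789.

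Among genes that moved in one direction in both steps, the largest rises were in the muscle genes Myom2, Pvalb and Flnc. Flnc rose by 5.01 and then by 4.1 on the log2 scale (edgeR adjusted p = 0.0273 and 0.0429). Its first step was at 1.55 without Con A 3 (edgeR adjusted p = 0.449), Pvalb at -0.62 (0.834) and Myom2 at 1.91 (0.671). The first step also lost its call without WT 1, 2 or 3 for Flnc (0.0792, 0.0703 and 0.0679), Pvalb (0.0746, 0.0897 and 0.0911) and Myom2 (0.0971, 0.0938 and 0.102). The second step lost it without each library but Con A 3 and FMT-Con A 2, for Flnc (0.0635 or more), Pvalb (0.0584 or more) and Myom2 (0.0563 or more). The largest joint falls were in Hsd3b5 (-3.03 and -2.88), a steroid dehydrogenase, Ccr3 (-1.96 and -2.52) and Serpina12 (-1.81 and -1.84). Hsd3b5 lost its second call without Con A 1 (edgeR adjusted p = 0.0628), FMT-Con A 1 (0.0767) or FMT-Con A 3 (0.061).

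FMT-Con A vs WT describes the sum of the transfer and the injection. As after the injection alone, all tested interferon-gamma targets and neutrophil markers were above WT, and 24 of 25 acute phase genes. Below it were 12 of 18 bile acid genes, 9 of 13 lipogenesis genes and 8 of 11 periportal genes, the last a list not called after the injection alone. With an estimated correlation, of these lists only the interferon-gamma response was called. Saa3, an acute phase gene of macrophages and injured liver, went from 12.8 ± 2.15 to 8330 ± 1390 CPM (log2 fold change 9.34, n = 3 each, edgeR adjusted p = 2.4e-07) and Lcn2 from 13.2 ± 1.28 to 6380 ± 1620 CPM (log2 fold change 8.92, edgeR adjusted p = 2.03e-07). Cyp7a1 was at 0.364 ± 0.166 against 104 ± 24.3 CPM (log2 fold change -8.16, edgeR adjusted p = 2.4e-07), and Nr1i3 at 1.56 ± 0.199 against 130 ± 8.41 CPM (log2 fold change -6.38, edgeR adjusted p = 2.4e-07). In all, 10449 genes passed (59%), 5517 higher and 4932 lower in FMT-Con A, 6646 of them by at least 2-fold, and the groups did not overlap for 69.1% of genes, where chance gives 10%.

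The largest rises were in Reg3b (34.6 ± 19.2 CPM against 0 counts, at least 727-fold higher, edgeR adjusted p = 9.97e-06) and in the muscle genes Art1, Myf6, Myl1, Smpx, Myh4, Myh1 and Smtnl1. Myh4, a fast-fibre myosin, was at 2630 ± 2080 CPM (log2 fold change 11.63, edgeR adjusted p = 0.00404), and all 23 tested skeletal muscle genes rose (median 10.74, or 10.55 with members at 0 set to their bound, camera adjusted p = 0.00227, and adjusted p = 0.62 with an estimated correlation). In Con A vs WT 19 of the 23 rose and Tnnt1, Tnni1, Actn3 and Neb did not pass (median 6.79, or 6.41 with the bound, camera adjusted p = 0.37). That rise came mainly from Con A 3 (list sum 2250 CPM, against 10.9 and 21.1 in Con A 1 and 2). Of 39.7 to 57.3 in WT, Neb gave 33.8 to 44.8. With FMT-Con A 1 and 3 removed, the edgeR adjusted p was 0.0774 for Art1, 0.0931 for Myf6 and 0.054 for Smpx. The largest falls after Cyp7a1 were in Mup4 (-7.5), Nr1h5 (-7), Nr1i3, Cx3cr1 (-6.38) and Hsd3b2 (-6.34).

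All 28 interferon-gamma response genes were above WT (28 adjusted over the list alone, median 3.34, camera adjusted p = 1.62e-33, and adjusted p = 0.0484 with an estimated correlation), with Cxcl9 at 6.97 and Gbp5 at 5.1, and Ifng rose by 4.4. The type I interferon list was mixed: 15 of 22 rose, Mx1 and Oas2 fell, and Oas3, Irf7, Ddx58, Ifih1 and Bst2 did not pass (15 and 2 adjusted over the list alone, median 1.23, camera adjusted p = 0.00165, and adjusted p = 0.552 with an estimated correlation). Mx1 was at 3.57 ± 0.82 CPM against 9.11 ± 0.98 in WT (log2 fold change -1.36, edgeR adjusted p = 0.00728). Of 23 cytokines and chemokines 21 rose, with Il18 lower and Il4 not passing (21 and 1 adjusted over the list alone, median 3.51, camera adjusted p = 1.08e-08, and adjusted p = 0.122 with an estimated correlation). Il10 rose by 1.34 (edgeR adjusted p = 0.0372), a call lost without WT 2 (0.117), WT 3 (0.0784) or FMT-Con A 2 (0.117). All 16 NF-kappaB targets rose (16 adjusted over the list alone, median 2.2, camera adjusted p = 1.1e-10, and adjusted p = 0.145 with an estimated correlation). So did 24 of 25 acute phase genes, all but Hamp, with Saa1 at 8.23 (24 adjusted over the list alone, median 3.89, camera adjusted p = 1.61e-36, and adjusted p = 0.0881 with an estimated correlation). Of 19 bacterial sensing genes 12 rose and Tlr5, Tlr7 and Tlr8 fell (12 and 3 adjusted over the list alone, median 0.72, camera adjusted p = 0.00047, and adjusted p = 0.136 with an estimated correlation), with the lipopolysaccharide co-receptor Cd14 at 7.6.

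Cell death genes rose in 18 of 22 cases (18 adjusted over the list alone, median 1.24, camera adjusted p = 4.32e-08, and adjusted p = 0.122 with an estimated correlation), with 4 not passing, among them Casp1, Casp8 and Cflar. Of 13 p53 targets 11 rose, with Plk2 and Bbc3 not passing (12 adjusted over the list alone, median 2.36, camera adjusted p = 4.16e-05, and adjusted p = 0.122 with an estimated correlation). Of 16 unfolded protein response genes 13 rose, the chaperone gene Hspa5 at 1.73 (15 adjusted over the list alone, median 1.62, camera adjusted p = 4.27e-06, and adjusted p = 0.136 with an estimated correlation). Immediate early genes rose in 13 of 19 cases and the hepatocyte growth factor gene Hgf fell (13 and 1 adjusted over the list alone, median 3.33, camera adjusted p = 2.4e-07, and adjusted p = 0.136 with an estimated correlation). Glycolysis and hypoxia genes rose in 10 of 13 cases (10 adjusted over the list alone, median 2.72, camera adjusted p = 6.91e-06, and adjusted p = 0.183 with an estimated correlation). Coagulation genes rose in 8 of 17 cases, with F5, F11, Proc and Serpinc1 lower (9 and 4 adjusted over the list alone, median 1.09, camera adjusted p = 0.0143, and adjusted p = 0.325 with an estimated correlation). All 13 neutrophil genes rose (13 adjusted over the list alone, median 5.19, camera adjusted p = 8.62e-13, and adjusted p = 0.136 with an estimated correlation). Of 12 monocyte genes 7 rose, with Cx3cr1 lower (8 and 1 adjusted over the list alone, median 1.25, camera adjusted p = 0.00168, and adjusted p = 0.122 with an estimated correlation).

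Bile acid synthesis and transport genes fell in 12 of 18 cases, while Baat and Abcc4 rose (12 and 2 adjusted over the list alone, median -1.43, camera adjusted p = 8.44e-05, and adjusted p = 0.247 with an estimated correlation). Of 13 lipogenesis genes 9 fell and 0 rose (9 adjusted over the list alone, median -1.48, camera adjusted p = 0.00112, and adjusted p = 0.325 with an estimated correlation). Of 11 periportal genes 8 fell, with Sds and Hsd17b13 higher (8 and 2 adjusted over the list alone, median -1.49, camera adjusted p = 0.00246, and adjusted p = 0.325 with an estimated correlation). Hal, which encodes histidine ammonia-lyase, fell by 2.9. G6pc, which encodes glucose-6-phosphatase, went from 207 ± 112 to 3.17 ± 0.411 CPM (log2 fold change -6.03, edgeR adjusted p = 6.29e-06). Alb was at log2 fold change -1.01 (edgeR adjusted p = 0.00226) and Lgr5 at -4.26. G6pc (ENSMUSG00000078650) lies on chromosome 11 at 101367561 to 101377903.

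The other 21 lists were not called against WT. They included P450 genes (11 of 18 lower, Cyp2b10 and Cyp3a13 higher, camera adjusted p = 0.0689, and 0.0479, 0.0249, 0.0141 and 0.0304 without WT 2, Con A 1, Con A 3 and FMT-Con A 2). Kupffer cell genes (6 of 12 lower, Marco higher) had a camera adjusted p of 0.118, and 0.00924 without FMT-Con A 2, and pericentral genes (7 of 11 lower, Glul higher) 0.118 and 0.0337. Adipocyte genes (Cidec and Plin4 higher of 7) had a camera adjusted p of 0.14, and 0.045 without WT 2. Antigen presentation (5 of 12 higher, B2m and H2-DMb1 lower, camera adjusted p = 0.148), T cell checkpoints (5 of 11 higher, Lag3 lower, camera adjusted p = 0.118) and T and NK cell genes (8 of 21 higher, Cd4 and Klrk1 lower, camera adjusted p = 0.123) held risers among many genes that did not pass. Chordc1 fell and 3 heat shock genes rose of 11 (camera adjusted p = 0.484), the fall losing its call without WT 1, WT 2, FMT-Con A 1 or FMT-Con A 2 (edgeR adjusted p = 0.133, 0.0763, 0.114 and 0.0896). NRF2 (5 higher, Hmox1 at 4.63, and 8 lower of 15, camera adjusted p = 0.326), cell cycle (5 higher and 9 lower of 25, camera adjusted p = 0.381) and fatty acid oxidation (7 higher and 8 lower of 23, camera adjusted p = 0.539, test direction down, median 0, mean -0.03) went both ways. So did cholesterol synthesis (8 higher and 4 lower of 21, camera adjusted p = 0.463), glucose handling (4 higher and 6 lower of 11, camera adjusted p = 0.155), the urea cycle (6 higher and 7 lower of 17, camera adjusted p = 0.206) and the clock (7 higher and 6 lower of 17, camera adjusted p = 0.463, test direction down, median 0.24, mean -0.12). Among cell markers, B and plasma cell genes had Ighm higher and Mzb1 lower of 11 (camera adjusted p = 0.894, test direction down, median 0.05, mean -0.04), and stellate cell genes 4 higher and 3 lower of 15 (camera adjusted p = 0.894, test direction up, median -0.13, mean 0.89). Sinusoidal endothelial genes had 4 higher and 5 lower of 15 (camera adjusted p = 0.82), cholangiocyte genes 5 higher and 1 lower of 7 (camera adjusted p = 0.341), hepatocyte genes Hnf4a and Fgl1 higher and 6 lower of 13 (camera adjusted p = 0.435) and erythroid genes 5 higher of 7 (camera adjusted p = 0.118). Of the 9 mitochondrial transcripts 8 fell, all but mt-Atp6 (median -1.03). Mki67 fell (log2 fold change -0.91, edgeR adjusted p = 0.014), a call lost without WT 2 (0.0606), FMT-Con A 1 (0.0519) or FMT-Con A 3 (0.0559). Adjusted over the list alone, the counts were equal to those given, except for heat shock (2 higher and 0 lower), B and plasma cells (0 either way) and hepatocytes (7 lower).

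Counts of genes ran from 9060 to 11349 with 1 library left out and came to 6957 with FMT-Con A 1 and 3 removed. With an estimated correlation the interferon-gamma response remained called and the other 16 lists did not, and other splits of the 6 libraries gave up to 23 called lists against 17.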

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

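The tests below of muscle, dilution, collection time and library identity were chosen after the results they address were seen. Counts over other splits were planned before.

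Transcripts of skeletal muscle, which no comparison was set up to measure, stood above every WT library in 4 of the 6 livers of injected mice. The 24 list genes summed to 2250 CPM in Con A 3, to 21500, 1980 and 21500 in FMT-Con A and to at most 57.3 in WT. At least 23 of the 24 genes were above the highest WT library in each of the 4, with Acta1 at 309 and Myh4 at 167 CPM in Con A 3 and Acta1 at 3070, 304 and 2770 CPM in FMT-Con A, which is consistent with muscle tissue or RNA mixed into the liver material. A response to the transplant is argued against for Con A 3, which received none and stood 39.3 times above the highest WT library. For FMT-Con A against Con A it stays open: the exact permutation p was 0.2 (the smallest possible is 0.1), since FMT-Con A 2 lay below Con A 3. Where muscle RNA would have entered is not in the labels, and 4 of the 24 list genes averaged at least 1 CPM in WT liver, such as Neb at 39.6, 33.8 and 44.8 CPM.

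Many interferon and inflammatory transcripts were lower in FMT-Con A than in Con A. Dilution of liver RNA by muscle RNA would lower liver transcripts alike and is argued against as the whole cause: the median of the type I interferon list lay 1.39 below that of the acute phase list (difference -1.39, interquartile ranges 1.05 and 0.67), and the muscle list took at most 2.15% of the counts. A difference in collection time between the groups may contribute and cannot be told apart from the transfer. The labels give no time of day or time after injection, and 9 of 17 clock genes passed the threshold between these groups. With 9 of the 17 higher and 6 lower in Con A vs WT, that comparison, the axis and the genes changed back share this limit. An effect of the transfer itself, which the design names, is open as well. With FMT-Con A 1 and 3 both removed, a single FMT-Con A library was left. The log2 fold changes of Mx1 (-2.78 against -3.12) and Ifng (-2 against -2.09) were then similar, but with SEs of 0.57 (from 0.36) and 0.47 (from 0.29).

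FMT-Con A 1 and 3 were closer to each other than any other pair of libraries. A library deposited again under another name is argued against, since their median chi-square was 2.53 times that of sampling. A single liver or RNA prepared as 2 libraries may account for it and cannot be told apart from a likeness of separate animals, because WT 1 and 2 came near with 3.08 and the labels do not describe the preparation of each library. If it applied, FMT-Con A would hold fewer independent animals than libraries and its p-values would be too small. Summed into 1 library, the pair left 766 genes between FMT-Con A and Con A, 765 of them among the 2981.

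With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled groups gave the most genes (1 of 10): 11219, 2981 and 10449 in the 3 comparisons, against at most 0, 2 and 0. Genes changed back numbered 1977 against 0 (1 of 10), bounded by those calls. Other splits mix the groups, which widens the spread on each side. Their low counts thus follow by construction and decide nothing. For gene lists, 6, 1 and 6 of 10 splits gave as many as the 19, 23 and 17 called (highest others 22, 21 and 23).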

How the results depend on the processing

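The muscle covariate, the summing of FMT-Con A 1 and 3, the removal of both and, for the axis, the omission of each Con A library were chosen after the data had been seen, and the other alternatives before. The covariate nearly marks FMT-Con A 1 and 3, so it and the removal of both are not separate checks. Of the values of named genes under the alternatives, 2477 of 2494 in Con A vs WT and 2233 of 2262 in FMT-Con A vs WT had the direction and the side of the threshold reported, but 1542 of 1987 in FMT-Con A vs Con A, where 423 lost the call, 18 gained it and 4 reversed. Size factors gave 11237, 2944 and 10454 genes in the 3 comparisons, no count filter 11893, 3589 and 11005, and the DESeq2 Wald test 11810, 3892 and 11004.

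The 2981 genes of FMT-Con A vs Con A became 1443 with at least a 2-fold change, 5726 with voom, 1156 with the 6 libraries of the groups, 450 with the covariate, 766 with the pair summed and 99 with both removed, which leaves a lone FMT-Con A library that is assumed to vary like the other groups. With single libraries left out they ran from 664 (without FMT-Con A 1) to 4053 (without FMT-Con A 2). FMT-Con A vs WT came to 6646 genes with at least a 2-fold change and 6957 with both removed. The 1977 genes changed back became 3678 with voom, 332 with the covariate, 598 with the pair summed, 76 with both removed, and 520 (without FMT-Con A 1) to 3011 (without Con A 2) with single libraries left out. A fold minimum lowers a count by construction. For the others the cause was not tested.

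Called lists numbered 1, 0 and 1 in the 3 comparisons with an estimated correlation, against 19, 23 and 17, and fry, which asks another question, called 31 in FMT-Con A vs WT. The axis difference of -0.126 was -0.14 with the 500 genes of lowest p. With single libraries left out it ran from -0.139 (without Con A 3) to -0.036 (without Con A 1), and from -0.129 to -0.121 over the planned omissions. Among single genes, Mki67 in Con A vs WT ran from -0.42 (without WT 3) to 0.15 (without WT 2) and Pvalb from -0.62 (without Con A 3, the Con A library with muscle transcripts) to 6.37 (without WT 1). In FMT-Con A vs Con A, Saa1 ran from -0.13 (without FMT-Con A 2) to 0.38 (without Con A 3) and was -0.08 with voom, and Sema6c was -1.14 with the covariate and -0.64 with both removed, against 3.88; the cause was not tested.

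With the muscle covariate or both libraries removed, 17 of the 23 lists of FMT-Con A vs Con A kept their call, and those for bile acids, P450 genes, the urea cycle, neutrophils, Kupffer cells and adipocytes lost it. Under both settings 6 other lists gained a call: heat shock, lipogenesis, sinusoidal endothelium and stellate cells down, and fatty acid oxidation and B and plasma cells up (camera adjusted p from 0.00296 for stellate cells to 0.048). In FMT-Con A vs WT, T and NK cells (0.0377 and 0.0428) and erythroid cells (0.00351 and 0.0038) gained one under both, and antigen presentation with both libraries removed (0.0428). A replicate block gave 11093, 2663 and 10207 genes and 1706 changed back, though same-numbered libraries were not alike across groups (correlations -0.22 to 0.34).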

Other observations

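The tests of sex-biased, complement, cardiac and control genes were chosen after the data had been seen. Of 15 male-biased liver genes Hsd3b5, Elovl3, Slco1a1 and Mup21 were lower in FMT-Con A than in Con A. The median was -0.73 (8 lower adjusted over the list alone, camera adjusted p = 0.000195, and adjusted p = 0.263 with an estimated correlation). Slco1a1 lost its call without Con A 1 (edgeR adjusted p = 0.0631), FMT-Con A 1 (0.0633) or FMT-Con A 3 (0.0617), as Hsd3b5 did. With the muscle covariate Slco1a1 (log2 fold change -0.82, edgeR adjusted p = 0.15, against -1.57), Hsd3b5 (-1.62, 0.219, against -2.88) and Elovl3 (-3.22, 0.0687, against -4.38) did not pass. Of the 15 genes 10 fell against WT (camera adjusted p = 0.00347, and adjusted p = 0.62 with an estimated correlation), and in Con A vs WT 5 fell and Cyp7b1 rose (camera adjusted p = 0.328). Hsd3b5 went from 188 ± 39.8 CPM in WT to 3.19 ± 2.7 in FMT-Con A (n = 3 each, log2 fold change -5.91). A shift from the male towards the female pattern of liver genes is a candidate explanation and would raise female-biased genes: of 8, 2 rose, among them Cux2 (1.76), and Hao2 fell (median 0.51, camera adjusted p = 0.311), a p that misses the threshold and excludes nothing. Against WT 3 of the 8 fell, and in Con A vs WT 5 (camera adjusted p = 0.508 and 0.329), and Cyp17a1 rose in both.

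Of 15 complement genes 10 rose and C8g fell after the injection alone (camera adjusted p = 0.247), C3, the central component, from 2060 ± 156 to 13200 ± 4970 CPM (log2 fold change 2.67). After the transfer 6 were lower than in Con A (median -0.46, camera adjusted p = 0.00262, and adjusted p = 0.263 with an estimated correlation), such as Cfb (-1.41), while C3 did not pass (-0.28, edgeR adjusted p = 0.474). Against WT 4 rose and C8a, C8g, C9 and Masp1 fell (camera adjusted p = 0.629).

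The labels give the animals as female in one place and male in another. Transcripts of the Y chromosome were present in all 9 libraries (Ddx3y at 107 to 272 and Eif2s3y at 47.7 to 119 CPM) and Xist lay at 0.95 to 6.78. Of the 5 sex check genes Ddx3y (-0.54) and Kdm5d (-1.22) fell in Con A vs WT, and Ddx3y, Kdm5d, Eif2s3y and Uty in FMT-Con A vs WT.

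Of 6 cardiac muscle genes Mybpc3 rose in Con A vs WT (camera adjusted p = 0.703), Actc1 in FMT-Con A vs Con A (camera adjusted p = 0.018, and adjusted p = 0.252 with an estimated correlation), and Myh6 and Mybpc3 in FMT-Con A vs WT (camera adjusted p = 0.56). Of 8 ubiquitously expressed control genes 7 rose and Tbp fell in Con A vs WT (camera adjusted p = 0.155), 2 fell in FMT-Con A vs Con A, among them Hprt (camera adjusted p = 0.0747), and 5 rose in FMT-Con A vs WT (camera adjusted p = 0.205).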
